A study of Homo sapiens with 3 samples.

How the data were processed

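Chromatin of untreated Huh7 cells was sequenced in 3 libraries: 1 input and 2 anti-FOXM1 ChIP libraries, replicates 2 and 3. Per the submitters' processing notes, CASAVA 1.4, BWA and MACS2 2.2.7.1 were used and the genome build was GRCh38. The notes used here give these tools no role or order, and filters and the handling of duplicate reads were not given in the sources used here. Each ChIP library had its own deposited list of peaks and its own deposited list of summits, so peaks stood per library and not on pooled reads.

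The deposited peak lists gave each peak a fold enrichment at its summit, a linear ratio over the local background with a pseudocount of 1, by the layout of the format. They also gave a deposited −log10 p and a deposited −log10 q at the summit. The deposited score was the −log10 q times 10, cut to a whole number, and was not used further. The deposited summit offset, of another kind of unit, gave the summit's place in bp from the peak start. The lowest −log10 q was 1.32 in replicate 2 and 1.31 in replicate 3, just above that of a q of 0.05. Peaks weaker than this were not in the lists, so the absence of a peak says only that the threshold was not passed.

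Whole fragment counts at each summit, the local background and the scale between ChIP and control were rebuilt from the deposited fold and −log10 p, a step chosen after seeing the data. Fold was taken as the scaled count plus 1 over the background plus 1, and p as the upper tail of a Poisson distribution with that background. All peaks of both libraries (100%) were rebuilt within 0.001 of the deposited −log10 p. Of simulated peaks 100% had the exact fragment count, while shuffling p left 1.30% rebuilt. The scale was 0.848 for replicate 2 and 0.869 for replicate 3. The labels do not state which library served as control in peak calling, and a control, taken to be the input, was inferred from scales below 1. Read as depth on that assumption, the ChIP libraries were 1.18 and 1.15 times as deep as the control, and replicate 2 was 1.02 times as deep as replicate 3. Intervals on counts and shares cover counting error only.

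Coordinates are 1-based on GRCh38. Gene positions came from a RefSeq gene table of the same build with 59094 records and no strand, exons or sequence. The start of a gene could therefore not be told from its finish, and the planned distance to a transcription start became the distance to either end of a gene. Exon, intron and UTR positions were not used here. The planned motif tests over 15 motifs and the background matched on promoter CpG content needed the genome sequence and were not run. Random positions were drawn between the first and last annotated gene of a chromosome, leaving out stretches of over 1 Mb without genes, in place of known assembly gaps.

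Peaks on chromosomes 1 to 22 and X were compared, leaving 41 peaks of replicate 2 and 45 of replicate 3 elsewhere. Peaks that overlapped by at least 1 bp were shared and were merged into loci, with the highest peak of each library giving the locus its fold. Chance overlap came from 1000 placements (one-sided permutation test). Differences of medians and correlations used 100000 resamples (two-sided permutation tests). The summit of a shared locus was the midpoint between the summits of the highest peak of each library, which could lie apart. A protein-coding gene was called bound where such a summit lay within 1 kb of either end. The 12 gene lists had 441 entries, all 441 matched in the gene table, and were compared with all other protein-coding genes by Fisher's exact test (two-sided) with Benjamini-Hochberg adjustment over the lists. Shares have exact Clopper-Pearson 95% intervals.

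The main comparisons and tests, the gene lists, the rule for named genes and the alternatives named next were fixed before the data were examined. The rule named FOXM1, the 20 bound genes of highest lower fold in the 2 libraries and up to 4 bound members of each list by the same rank. It also named the 10 strongest shared loci by that rank, with the nearest protein-coding gene. Not every gene the rule names is reported here. These alternatives were stricter thresholds on q and fold, other definitions of a shared locus, windows of 500 bp and 5 kb, ends of all gene types and each library alone, each for the results it was planned for. Added after seeing the data were the placements near the original position or at other gene ends, and list backgrounds matched on chromosome, local gene density or gene length (10000 draws each). Also added then were the list tests with summits within 100 bp, the counts of bound and of named genes under each alternative, and the comparisons of chromosomes, segments and gene families. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Overlap counts were checked against bedtools 2.31.1, with a difference of 0.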

Results

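FOXM1 is a forkhead transcription factor known for driving genes of the G2 and M phases of the cell cycle. Its chromatin occupancy was measured by ChIP-seq, the sequencing of DNA fragments pulled down with an antibody, in untreated Huh7 cells, an established human hepatocellular carcinoma line. The series held 3 samples: 1 input library, for which no peak list was used here, and 2 libraries made with the anti-FOXM1 antibody G-5, numbered replicate 2 and replicate 3 in their titles. The labels do not say whether the ChIP libraries came from separate cultures, and p-values, which are over peaks, loci, genes or segments, describe these lists and not the spread between samples. Replicate 2 had 8271 peaks and replicate 3 had 11502, with median widths of 227 bp and 229 bp. Median fold enrichment was 3.76 in replicate 2 and 3.78 in replicate 3, and the highest values were 8.09 and 9.58. Fold and −log10 q are the authors' own values for each peak. Total read counts were not used here. Fragment counts over the summits, rebuilt from the deposited fold and p, had medians of 26 in replicate 2 and 24.5 in replicate 3, so a typical peak rested on few fragments.

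The first question was which regions both libraries called. Shared loci were ranked by the lower fold of the 2 libraries. A low local background raises this rank as a high fragment count does. The strongest by this rank lay beside KMT2A, which encodes a histone H3 lysine 4 methyltransferase, and B4GALT7, which encodes a galactosyltransferase of proteoglycan synthesis. At KMT2A (GRCh38 chromosome 11, 118435991 to 118436825) fold enrichment was 7.83 in replicate 2 and 8.09 in replicate 3, with the summit 117 bp outside the annotated gene. At B4GALT7 (chromosome 5, 177599890 to 177600313) it was 7.55 and 7.45, with the summit 48 bp outside the gene. Of the peaks on chromosomes 1 to 22 and X, 5716 of replicate 2 (69.5%) and 5669 of replicate 3 (49.5%) overlapped a peak of the other library, and they merged into 5357 shared loci.

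The other loci among the 10 strongest were mostly at ends of protein-coding genes. HP1BP3, which encodes a heterochromatin protein 1 binding protein, had its summit 599 bp inside the gene (chromosome 1, 20786448 to 20786975; fold 7.76 and 6.85). Its −log10 q of 23.7 in replicate 2 and 18.8 in replicate 3 exceeded the 18.1 and 15.7 at KMT2A. SCRIB, a cell polarity gene, shared its locus with PUF60, a splicing factor gene (chromosome 8, 143815144 to 143816392; fold 7.21 and 6.47). ODC1, the rate-limiting enzyme of polyamine synthesis, had fold 6.89 and 6.41 (chromosome 2, 10447983 to 10448335, inside the gene). The forkhead gene FOXK2 had fold 6.45 and 6.09 (chromosome 17, 82519216 to 82519711). SH3BGRL3 (chromosome 1, 26279791 to 26280398) had 6.77 and 6.42, TRAPPC3 (chromosome 1, 36155880 to 36156694) had 6.29 and 5.96, and SRRM3 (chromosome 7, 76201758 to 76202049) had 7.25 and 5.90. The exception lay inside the ribosomal RNA gene RNA45SN2 (chromosome 21, 8213259 to 8213391), with fold 7.09 and 8.55, and 383710 bp from the nearest protein-coding gene. It rested on 32 and 37 rebuilt fragments over backgrounds of 2.97 and 2.88, the lowest of each library. Whether reads there map to 1 place alone was not examined, so this fold may not reflect occupancy.

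Overlap under each placement tried was far below the observed number. Random placement of one library's peaks on the same chromosomes gave 25.3 ± 5.0 shared loci (SD over 1000 placements), and the permutation p was 0.001, the smallest the placements can give. Moving peaks by 10 to 100 kb gave 78.9 ± 8.30, and moving gene-end peaks to other gene ends of the chromosome gave 489 ± 19.7, each again with the smallest permutation p of 0.001. Those ends were drawn from both ends of every protein-coding gene. Lists that favour the same kind of gene end would overlap more by chance, and this was not tested. Across shared loci, log2 fold enrichment of the libraries correlated with Spearman's rho of 0.395 and Pearson's r of 0.420 (permutation p = 1e-05 for each, the smallest that 100000 resamples can give). This relation is across loci, which are not independent replicates. Both folds are also divided by a local background taken to come from the same control. That alone can make them correlate, and its part in the value was not tested. The count of shared loci depends on what counts as shared: requiring summits within 100 bp gave 3010 loci and reciprocal overlap of at least 50% gave 3339.

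Shared peaks had higher fold enrichment than unshared peaks in each library. In replicate 2 the medians were 3.83 and 3.59, a difference of 0.235, and in replicate 3 they were 3.93 and 3.66, a difference of 0.270 (permutation p = 1e-05 in each, the smallest possible, two-sided). With both lists cut to −log10 q of at least 5, a peak was shared only if its partner also passed that cut. The difference was then -0.0936 in replicate 2 (permutation p = 0.00236) and -0.0500 in replicate 3 (permutation p = 0.194). Over the full lists, the share of replicate 3 peaks with a partner was 83.3% in the strongest 10% by −log10 q and 30.98% in the weakest 10%.

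**Figure D1:**
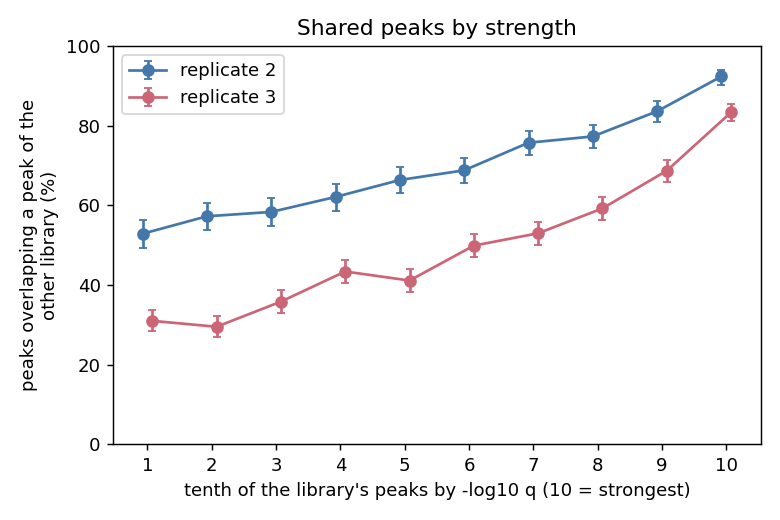
The percent of each library's peaks that overlap a peak of the other library (vertical axis) is plotted for 10 equal classes of its peaks ranked by −log10 q (horizontal axis, 10 the strongest), with bars giving exact 95% binomial intervals. In replicate 3 the strongest class stands at 83.3% and the weakest at 30.98%.

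At shared loci the rebuilt fragment counts of the libraries differed by less than counting error. The scatter was 0.578 times the counting variance at the 152 loci with at least 100 fragments in both libraries together, and 0.411 times over all 5357 loci. These counts are maxima at loci selected for a call in both libraries, and the effect of that selection on the scatter was not tested. Whether the libraries were separate immunoprecipitations is therefore not settled here. They were not merged, since no other pair of libraries was there for comparison, and each library's value is given throughout.

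The second question was where in the genome the shared loci lay. Of the 5357 loci, 3705 had their summit within 1 kb of an end of a protein-coding gene, which is 69.2% (exact 95% interval 67.9 to 70.4), against 3.23% of random positions. The reference gave no strand, so either end of a gene counted and a gene's start could not be told from its finish. Loci inside protein-coding genes but away from their ends made up 18.4%, against 43.4% of random positions, and loci between genes made up 4.20%, against 36.8%. The permutation p for the share at gene ends was 0.001, the smallest possible, against both random positions and loci moved by 10 to 100 kb (6.43%). The median distance from a summit to the nearest protein-coding gene end was 357 bp, against 43524 bp for random positions.

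**Figure D2:**
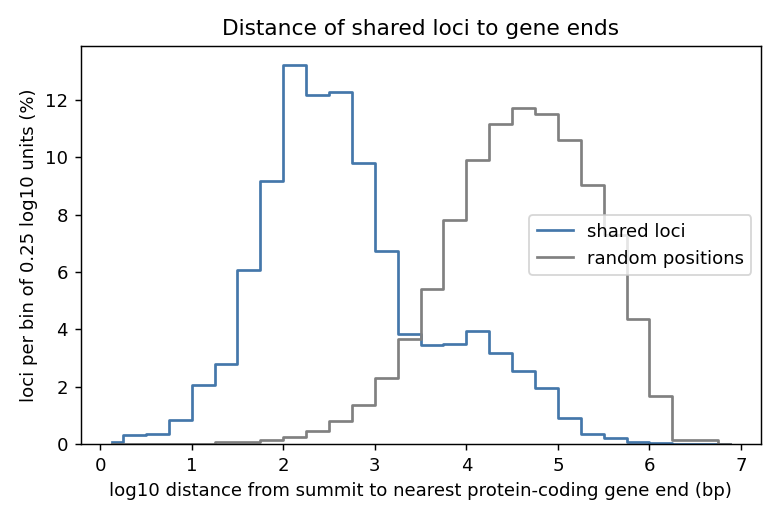
The percent of shared loci (blue) and of random positions (grey) in each bin of 0.25 log10 units (vertical axis) is plotted against the log10 distance in bp from summit to nearest protein-coding gene end (horizontal axis). Shared loci have a median distance of 357 bp and random positions one of 43524 bp.

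The third question was which genes carried a shared locus within 1 kb of an end, called bound below. The word stands for the peak call alone. The series held no library made with another antibody or from cells without FOXM1, and the motif tests were not run. Whether the peaks are specific to FOXM1 was therefore not tested. These were 3821 of 19970 protein-coding genes (19.1%). A locus within 1 kb of the ends of several genes counted for each of them. Among the list members named below, TACC3, POLE, XPC, XRCC3, RPS18 and GRIN1 shared their locus with another protein-coding gene. To which gene such a peak belongs was not tested. Beyond the loci above, the 20 bound genes with the highest lower fold of the 2 libraries included UNC5B, a netrin receptor gene (fold 5.81 in replicate 2 and 8.07 in replicate 3), and OAZ2, which encodes an inhibitor of ornithine decarboxylase (5.73 and 6.04). They also included GREB1, known as an estrogen-responsive gene (5.71 and 6.19), GPSM2, which acts in spindle orientation (5.68 and 6.92), and LMBR1 (5.94 and 5.66). PYGO2, a Wnt pathway coactivator gene, and SHC1, an adaptor gene of receptor tyrosine kinase signalling, shared a locus (7.84 and 5.67). MAP7D1 shared the locus of TRAPPC3, and FAM229A shared one with TSSK3 (6.53 and 5.81).

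FOXM1 itself was not among the bound genes. Its nearest shared peaks lay inside the gene (chromosome 12, 2857680 to 2877174), at 1372 bp from the lower coordinate end in replicate 2 (fold 3.42) and 1028 bp in replicate 3 (fold 4.41). These peaks overlapped by 3 bp and their summits were 344 bp apart, and they also lay within the overlapping gene ITFG2. At the opposite end, replicate 3 alone had a peak, 128 bp inside FOXM1 and also within RHNO1, with fold 3.49. Its −log10 q was 5.10, on 35 rebuilt fragments. The shared peaks had lower values, 2.86 on 23 fragments in replicate 2 and 4.19 on 20 in replicate 3.

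Genes of the G2/M list were not bound detectably more often than other genes. Of 59 members 13 were bound (22.03%, exact 95% interval 12.3 to 34.7), against 19.1% of other genes, an odds ratio of 1.20 (95% interval 0.592 to 2.25; Fisher's exact p = 0.618, adjusted p = 0.927). The bound members of highest fold were KIF23, a kinesin of the central spindle (4.69 in replicate 2 and 4.51 in replicate 3), TACC3, a spindle protein (4.58 and 4.36), FAM83D (4.32 and 4.36) and MKI67, the proliferation antigen Ki-67 (5.88 and 4.25). In simulations with an odds ratio of 3 set for this list over the 19970 genes, 96.0% of 200 runs had unadjusted p under 0.05, and 69.5% did with an odds ratio of 2. With summits required to lie within 100 bp, a rule applied to the lists after seeing the data, 11 of 59 members were bound, and the odds ratio was 1.89 (95% interval 0.885 to 3.70).

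Of the G1/S and DNA replication list 12 of 51 members were bound (23.5%; Fisher's exact adjusted p = 0.813), among them POLE (4.85 and 4.28), CDC25A (4.09 and 4.11), CCNE1 (3.92 and 5.47) and E2F8 (4.27 and 3.74). Of 36 DNA repair genes 4 were bound (11.1%; Fisher's exact adjusted p = 0.696): XPC (4.13 and 3.64), XRCC3 (3.62 and 5.68), NBN (3.81 and 3.40) and PARP1 (3.32 and 4.86). Of 24 p53 target genes 7 were bound (29.2%; Fisher's exact adjusted p = 0.601), including GDF15 (5.66 and 5.42), PLK3 (4.65 and 4.65), SESN2 (5.78 and 4.41) and MDM2 (4.35 and 4.24). None of these lists passed the test.

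Markers of blood and immune cells were the only list whose share differed after adjustment over the 12 lists. None of its 37 members, such as CD3E and PTPRC, was bound, which leaves an exact 95% upper limit of 9.49%, against 19.2% of other genes (Fisher's exact p = 0.000569, adjusted p = 0.00683). The call ended with −log10 q of at least 5 (adjusted Fisher's exact p = 0.616), fold of at least 5 (adjusted Fisher's exact p = 1) and summits within 100 bp (adjusted Fisher's exact p = 0.329), where far fewer genes of any kind were bound. Neuronal markers, which hepatocytes also lack in the main, had 5 of 28 bound (17.9%; Fisher's exact adjusted p = 1), including MAPT (5.38 and 5.46), DLG4 (4.24 and 3.83), SYP (3.70 and 3.58) and GRIN1 (3.56 and 3.50).

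Genes for hepatocyte products were bound in 4 of 50 cases (8%, odds ratio 0.367; Fisher's exact p = 0.0467, adjusted p = 0.187), so the lower share did not pass after adjustment. They included RBP4 (4.27 and 5.89), APOB (3.98 and 3.62) and ASS1 (2.56 and 3.38). The ASS1 call was marginal in replicate 2, with −log10 q of 1.82 against a lowest value of 1.32, and had 4.22 in replicate 3. With replicate 3 alone the list's difference from other genes was -20.2 percentage points and passed (adjusted Fisher's exact p = 0.00804). Of 22 hepatocyte transcription factor genes 4 were bound (18.2%; Fisher's exact adjusted p = 1), led by CEBPA, which had the highest fold of any replicate 2 peak (8.09, and 5.60 in replicate 3; chromosome 19, 33301543 to 33304031), and followed by CEBPB (4.79 and 3.93), HHEX (3.83 and 5.40) and RXRA (4.14 and 2.87).

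Of the Wnt, invasion and stemness list 11 of 33 members were bound (33.3%, odds ratio 2.12; Fisher's exact p = 0.0460, adjusted p = 0.187), which also did not pass after adjustment. Its difference from other genes was 14.2 percentage points, against 5.29 within 500 bp of a gene end and 15.7 within 5 kb. The members of highest fold were EPCAM (4.70 and 5.40), CTNNB1, which encodes beta-catenin (5.16 and 4.69), SOX9 (4.11 and 4.14) and LOX (4.04 and 4.46). Of 22 glycolysis genes 6 were bound (27.3%; Fisher's exact adjusted p = 0.813), including PFKL (5.76 and 4.81), PFKFB3 (4.12 and 4.75), PKM (3.75 and 4.84) and PDK1 (3.39 and 4.39). Of 24 cholesterol synthesis genes 4 were bound (16.7%; Fisher's exact adjusted p = 1): SREBF2 (4.59 and 5.24), INSIG1 (4.20 and 3.93), DHCR7 (3.14 and 3.47) and SQLE (2.40 and 2.62). The SQLE call was marginal, with −log10 q of 1.58 in replicate 2 and 2.25 in replicate 3, against lowest values of 1.32 and 1.31. Of 55 ribosomal protein genes 11 were bound (20.0%; Fisher's exact adjusted p = 1), including RPS18 (6.31 and 4.74), RPL13 (4.67 and 4.89), RPS15 (5.12 and 4.08) and RPS20 (4.92 and 4.02).

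**Figure D3:**
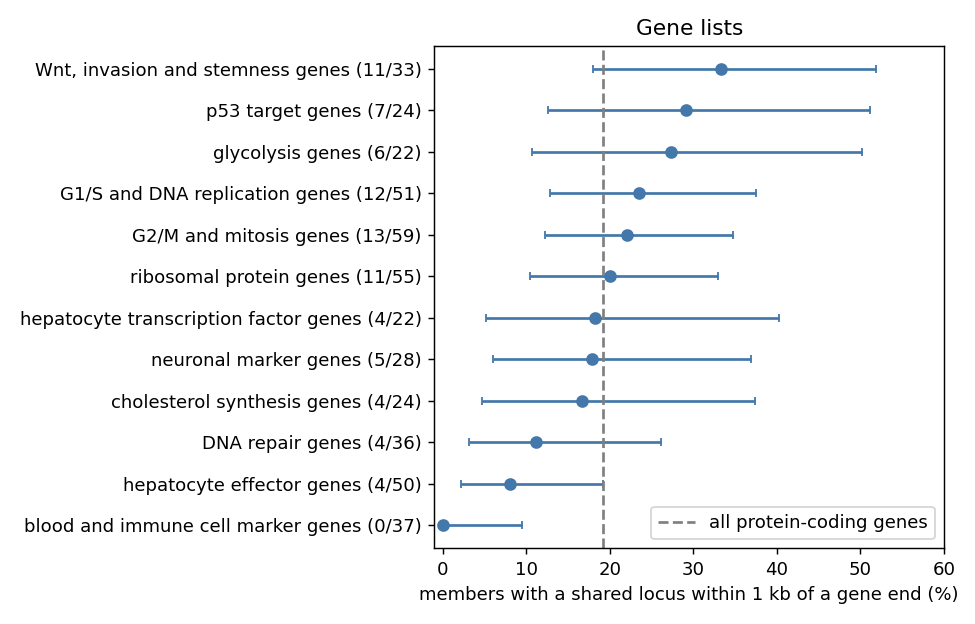
The percent of members with a shared locus within 1 kb of a gene end (horizontal axis) is plotted for each of the 12 gene lists, with bound over total members in the label, exact 95% binomial intervals as bars and the 19.1% of all protein-coding genes as the dashed line. The blood and immune cell markers stand at 0%, with an upper limit of 9.49%, and the G2/M list at 22.03%.

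Bound genes were spread unevenly over chromosomes, a comparison added after seeing the data. On chromosome 20, 192 of 537 protein-coding genes were bound (35.8%, exact 95% interval 31.7 to 40.0), on chromosome 22 it was 28.8% and on chromosome 9 it was 28.4%. On chromosome 5 the share was 13.0%, on chromosome 21 it was 12.1%, and on X it was 2.59% (22 of 848). On chromosome 11 the stretch from 65 to 70 Mb had 74 of 140 genes bound (52.9%) and 127 of the chromosome's 313 shared loci. The median control background rebuilt at its peaks was 12 fragments, against 5.0 over all peaks of each library, and the median lower fold of its shared loci was 2.85.

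**Figure D4:**
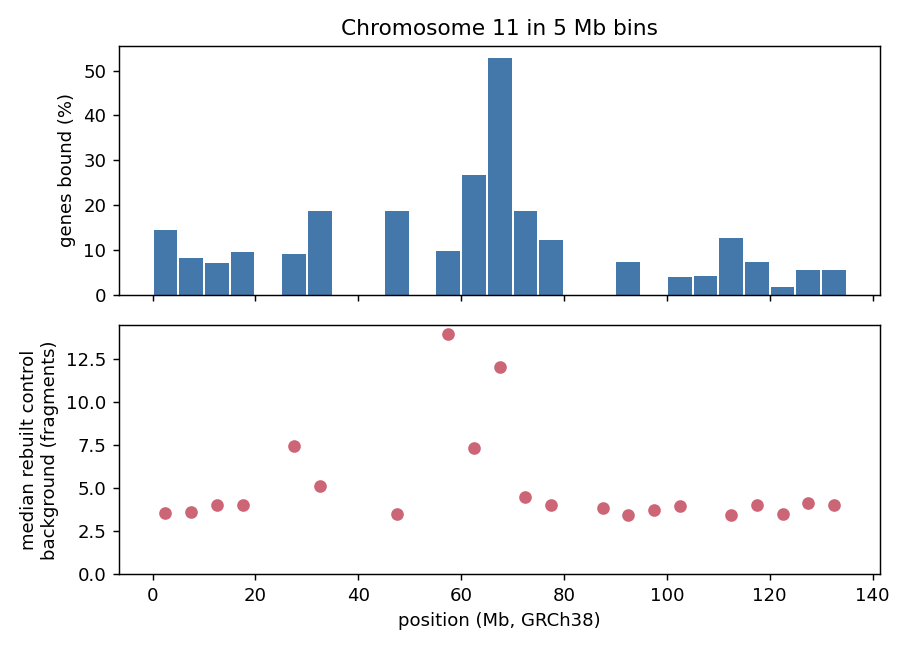
The percent of protein-coding genes bound (upper panel) and the median control background rebuilt at the peaks of both libraries, in fragments (lower panel, bins with at least 5 peaks), are plotted along chromosome 11 in bins of 5 Mb. The bin from 65 to 70 Mb has 52.9% of genes bound and a background of 12, and the bin from 55 to 60 Mb has 9.73% and 13.9.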

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

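Peaks outside chromosomes 1 to 22 and X entered no comparison. On unplaced and unlocalised scaffolds replicate 2 had 39 peaks and replicate 3 had 41. Of these, 12 in replicate 2 and 16 in replicate 3 lay on the single scaffold KI270733.1. The highest −log10 q of each library was there, 40.3 in replicate 2 (position 124666 to 124967) and 36.8 in replicate 3 (129985 to 130154), against highest values of 26.1 and 25.9 elsewhere. The highest fold of replicate 3, 9.58, was also on this scaffold. No explanation was tested for these peaks. Groups of 2 libraries were too small to test for a library that stands apart.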

How the results depend on the processing

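The matched backgrounds, the nearby placements and those at other gene ends were chosen after seeing the data. So were the list test with summits within 100 bp, and under each alternative the G2/M odds ratio and counts of bound genes. The correlation across shared loci and the share of shared loci at gene ends kept their direction and passed their permutation tests in every alternative run. For fold, rho was 0.619 with −log10 q of at least 5 and 0.493 with summits within 100 bp. With −log10 q in place of fold it was 0.310. The share at gene ends ran from 56.95% to 82.5%, and from 63.4% to 65.98% with a library left out. The motif alternatives and CpG-matched background need the genome sequence and were not run. No paired analysis was possible because no test compared groups of libraries. Summits held a median of 26 and 24.5 fragments, which limits the detection of weak peaks. Of 169 values under an alternative, 125 kept direction and call or, for counts, stayed within 1.5 times. Some did so by construction, and lists that did not pass kept only their sign.

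For the changes below the cause was not tested, except that stricter rules leave fewer peaks by construction. Shared loci fell to 1128 with −log10 q of at least 5, to 150 with fold of at least 5, to 3339 with reciprocal overlap of at least 50% and to 3010 with summits within 100 bp. The difference of shared from unshared peaks in median fold became -0.0936 in replicate 2 and -0.0500 in replicate 3 with −log10 q of at least 5. Peaks with only a weaker partner then counted as unshared. Bound genes numbered 882, 112 and 2162 with the q, fold and summit rules, and 5022 to 6411 with a library left out. Lists that passed numbered 0 under each of the q, fold and summit rules, and 1 to 2 with a library left out.

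The lists' differences from other genes are in percentage points. With −log10 q of at least 5 they were -2.46 for G1/S, 4.68 for hepatocyte transcription factor, -1.39 for Wnt, 3.92 for cholesterol, -0.782 for ribosomal and 2.73 for neuronal genes, each reversed without passing, and -4.42 for immune markers, no longer passing. With fold of at least 5 only 112 genes were bound, and lists with no bound member stood at the base rate below 0 by construction, which shows no reversal: -0.563 for G2/M, -0.562 for G1/S, Wnt, ribosomal and immune genes and -0.561 for glycolysis. Hepatocyte transcription factor and neuronal genes stood at 3.99 and 3.01 there, without passing. With summits within 100 bp they were 7.84 for G2/M genes (main value 2.91), not passing, -10.8 for immune markers, no longer passing, and 3.46 for neuronal genes, reversed. Hepatocyte transcription factor genes reversed to 2.26 within 500 bp and 8.15 within 5 kb, where cholesterol and neuronal genes reached 1.33 each, and ribosomal genes to -0.0985 against genes matched on chromosome. With a library left out the ranges were -20.2 to -15.2 for hepatocyte effector genes, which passed in replicate 3 alone, 2.13 to 13.4 for hepatocyte transcription factor genes and 8.20 to 9.58 for cholesterol genes. Other lists moved by over 1.5 times without a change of call: 12.4 to 22.1 for p53 (main value 10.0), 7.30 to 14.3 for Wnt (14.2), 2.13 to 17.9 for glycolysis (8.15), 7.13 to 16.1 for G1/S (4.41), 6.10 to 11.2 for ribosomal (0.869), -11.3 to -1.55 for DNA repair (-8.04), 3.50 to 8.78 for G2/M (2.91), -7.11 to -3.72 for neuronal genes (-1.28) and -29.5 to -22.5 for immune markers (-19.2), which passed in each library alone.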

Other observations

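Gene families grouped by the letters that open their symbols were tested after the data were seen, 214 families of at least 12 genes in all. Fisher's exact test treats genes as independent, and families were not matched on chromosome or segment, over which the share of bound genes differed. The p-values may therefore be too small where members of a family lie close together. None of the 392 olfactory receptor genes (OR), 94 keratin-associated protein genes (KRTAP), 55 keratin genes (KRT) or 39 beta-defensin genes (DEFB) was bound, with Fisher's exact adjusted p of 8.34e-35, 3.24e-07, 0.00114 and 0.0155. Bound more often than other genes were the DENN domain genes, with 10 of 17 (58.8%; Fisher's exact adjusted p = 0.0155), such as DENND4B and DENND1A, and the ubiquitin-conjugating and ligase genes named UBE, with 17 of 42 (40.5%; Fisher's exact adjusted p = 0.0336), such as UBE2C, UBE2S and UBE3A. Zinc finger genes named ZNF had 69 of 517 bound (13.3%, against 19.3% of other genes; Fisher's exact adjusted p = 0.0190). Genes named CD had 6 of 91 bound (6.59%; Fisher's exact adjusted p = 0.0336), among them CD9 and CD47.

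The tests of explanations and hypotheses in the rest of this part were chosen after the results they bear on had been seen, at least in part, while the share of each gene list and its exact test under the main setting were planned. As a hypothesis, peaks at gene ends may lie at the 5′ end. Genes with an annotated divergent transcript, named with the suffix DT and read from the opposite strand next to the 5′ end, show which end that is. Of 490 such genes longer than 5 kb, 153 had a shared locus at the end facing the divergent transcript alone and 2 at the far end alone (exact McNemar p = 5.29e-43). This holds for genes with such a transcript, and was not tested for others. A second hypothesis, that bound G2/M genes may carry higher fold than other bound genes, was left open: their median lower fold was 3.74 over 13 genes against 3.61 over 3808, a difference of 0.128 (permutation p = 0.591).

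Many peaks of replicate 3 had no partner in replicate 2. Greater depth of replicate 3 is argued against, since the rebuilt depth of replicate 2 was 1.02 times that of replicate 3. Position near the calling threshold is a candidate explanation, since 83.3% of the strongest 10% of replicate 3 peaks had a partner against 30.98% of the weakest 10%, though mean width also differed, at 491 bp and 223 bp. Width is argued against as the whole cause, since a replicate 2 summit lay within 100 bp of 46.8% of the strongest 10% and 14.7% of the weakest 10%. Why replicate 3 had more peaks at slightly lower depth stays open, and no biological explanation was tested, because the labels give the libraries the same treatment.

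The share of bound members ran from 0% of immune markers and 8% of hepatocyte effector genes to 33.3% of the Wnt, invasion and stemness list, and only immune markers passed after adjustment. Whether G2/M genes had a preference of at least 3 times in odds stays open: the odds ratio of 1.20 had an upper 95% limit of 2.25, but with summits within 100 bp 11 of 59 members were bound, with an odds ratio of 1.89 and an upper limit of 3.70, and with −log10 q of at least 5 the upper limit was 4.29. Whether peaks follow how strongly genes are transcribed stays open: ribosomal protein genes had an odds ratio of 1.06, but its upper 95% limit of 2.08 does not exclude 2. Promoter CpG content and expression in these cells were not analysed here and could also set the shares.

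Segments of the genome differed in the share of genes bound. One candidate explanation is that segments with more control fragments, for example through extra copies, give more calls: across 473 bins of 5 Mb with at least 10 genes and 5 peaks the share rose with the median rebuilt background (Spearman's rho 0.508, Pearson's r 0.432, permutation p = 1e-05, the smallest possible), as it did given genes per bin (rank correlation 0.509) and over 171 bins with background from peaks over 5 kb from any gene end (rho 0.338, permutation p = 1e-05 each). Background is known only at called peaks, so 51 of 524 bins with at least 10 genes, with a median share of 0%, were left out, neighbouring bins are not independent, copy number was not measured and the labels do not state which library was the control. Across the 23 chromosomes the relation was not settled, with rho of 0.382 for the background of replicate 3 (r 0.423, permutation p = 0.0724 and 0.0445), and 0.204 without chromosomes 20 and 21 (r 0.114, permutation p = 0.370 and 0.622), and rho of 0.422 for replicate 2 (r 0.335, permutation p = 0.0456 and 0.117), and 0.451 without chromosomes 11 and 20 (r 0.271, permutation p = 0.0421 and 0.233): X had 2.59% of genes bound at a background of 5.0, and chromosome 11 had 16.2% at 7.09 in replicate 2. Stronger enrichment on such segments could not be judged: lower fold fell with the share (rho -0.309, permutation p = 1e-05), but the calling threshold admits lower folds where background is high, and given background the rank correlation was 0.0326 (permutation p = 0.561).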
